A study of Drosophila melanogaster with 21 samples.

How the data were processed

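Poly(A) RNA of Drosophila S2R+ cells was selected in repeated rounds with oligo-dT and made into Illumina TruSeq libraries, per the labels' protocols. Groups were taken from the sample titles. They were Control, Ime4, CG7818, Ime4 with CG7818, Fl2d, CG6422 and YT521, with 3 libraries each and 21 in all. For the libraries of the double depletion the genotype field names only Ime4, while the title and the treatment protocol name both genes, and the title was followed.

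The deposited values are raw read counts per gene, one table per library, with 17558 gene IDs and 5 summary lines that name no gene. Per the submitters' processing notes, the authors used CASAVA 1.8.4, STAR 2.4.0h, HTSeq 0.6.1 and DESeq2 1.6.3 with the build BDGP6. The strand setting of the counting and the release of the gene annotation are not given in the sources used here. The summary lines stayed out of library sizes and tests. Relative to all counted reads, the line for reads aligned to several places held 11.0% to 18.7% (median 15.0), that for reads outside any gene 1.46% to 1.91% (median 1.82) and that for ambiguous reads 0.72% to 0.89% (median 0.79), and the lines for low quality and for unaligned reads held 0. Counts assigned to genes came to 20214568 to 28296393 per library (median 22126193), and the 10 most abundant genes took 8.62% to 18.2% of them (median 17.0). A gene at 1 CPM thus rested on about 22.1 counts in the median library. Reads carried no molecular identifiers. The chi-square per degree of freedom between replicate libraries of a group was 4.52 to 231, so no pair of libraries lay within sampling noise of each other.

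Gene symbols, coordinates, biotypes and exon lengths came from Ensembl release 115 for BDGP6.54, whose gene models are later than those used for counting. Of the 17558 IDs 17252 had an entry, and the 306 without one took 3.95% of counts and are given by ID. The exon length of a gene is that of its merged exons in this annotation, known for 97.9% of the genes tested. GC content was not analysed here.

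All groups entered one fit, since they then share one estimate of the spread. Genes were filtered with edgeR's filterByExpr with a minimum count of 10, which left 8360 genes, 7730 of them protein coding, 357 non-coding and 177 without an entry. Libraries were scaled with TMM, and edgeR 4.0.16 fitted a quasi-likelihood model with one mean per group (R 4.3.3, prior count 0.125, residual degrees of freedom 14). The common biological coefficient of variation was 6.37%. Each depletion was compared with the control, and the CG7818 and Ime4, the double and Ime4, the double and CG7818, and the YT521 and CG6422 depletions with each other. A gene was called where the Benjamini-Hochberg adjusted p over all genes tested lay under 0.05. The median log2 fold change of all genes lay within 0.015 of 0 in every comparison. CPM values are counts-per-million of the TMM-scaled library, and principal components were computed on log2 CPM with a prior count of 2.

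The genes named in the text were chosen by a rule fixed before the values were seen. It takes the 5 targets in every comparison, the 7 highest and 7 lowest called genes of each comparison with the control and the 4 highest and 4 lowest of each direct comparison, among genes with a mean of at least 1 CPM and groups without overlap. From each list it takes up to 4 called members with the smallest p, or up to 2 members not called as values, and from the shared sets up to 8 genes. The text gives part of these genes, with preference for those whose call held in every alternative, and the rest are not reported here. Of the 572 values selected 496 passed the test.

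The lists were 25 sets fixed before the data were examined: m6A writer complex and readers, sex determination and dosage compensation, neural fate, axon guidance and adhesion, synapse and excitability, Notch pathway, splicing regulators, mRNA decay, RNA interference and antiviral defence, cytosolic ribosomal proteins, mitochondrial respiratory chain, unfolded protein and integrated stress responses, heat shock and chaperones, apoptosis and p53 targets, cell cycle and DNA replication, innate immunity, integrin, matrix and cytoskeleton, ecdysone response, insulin and TOR signalling, glycolysis, plasmatocyte markers, and markers of muscle, of germline and follicle cells, of crystal cells and lamellocytes, and of fat body and gut. Of 825 members 792 were matched to a gene ID. Among those not matched, and thus not tested in their lists, were InR, S6k, Tor and Lobe of insulin and TOR signalling. So were Dl, Psn and nrarp of the Notch pathway and Dcp1, Dcp2, Ge-1 and nos of mRNA decay. Each list was tested with limma's camera (limma 3.58.1) at the preset correlation of 0.01, with Benjamini-Hochberg adjustment over 150 tests, and counts of called members are given over all genes and adjusted over the list alone. Alternatives were an estimated correlation and limma's fry, which tests whether the genes of a list move on balance one way and compares them with no other genes.

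Sharing between depletions was counted as genes called in both, per direction. All comparisons with the control use the same 3 control libraries. In 20 simulated data sets all 21 libraries, the controls included, were therefore drawn anew around the control means without any change. The deviations of the real control libraries are thus not in them. A simulated comparison called at most 3 genes, so the simulation cannot tell how much shared controls add to longer lists of calls. The overlap of independent lists is n1 × n2 / N per direction.

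The steps were tested on simulated counts drawn from the means and library sizes of these samples. For the comparison of Ime4 with the control, over 8360 genes with 200 changed, edgeR recovered 59 of 67 genes (88.1%) at a log2 change of 0.5, 59 of 67 at 1 and 62 of 66 (93.9%) at 2, with 5 false calls among 185. DESeq2 1.42.0 made 190 calls, 12 of them false. With a simulated trend in gene length, the length correction recovered 56 of 67 (83.6%), 58 of 67 (86.6%) and 62 of 66 with 6 false calls among 182, against 908 false calls among 1086 with the trend left in. For the pair of the Ime4 and CG7818 depletions, 104 of 120 genes changed in both were recovered as shared. In data simulated for the YT521 depletion camera gave 2.8e-177 for a shifted list and 0.55 for an unshifted one.

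Alternatives fixed beforehand were DESeq2's size factors, DESeq2's Wald test, no filter, a stricter filter (at least 5 CPM in at least 3 libraries), a fit of the 2 compared groups alone, a robust fit, the replicate number as a block, an absolute log2 fold change of at least 1, and each library of the compared groups left out in turn. For shared calls they were the size factors, an adjusted p under 0.01 and the block. Alternatives added after the data were seen were the log2 mt:lrRNA share as a covariate, both libraries with a low mt:lrRNA share left out, and a correction for the trend with gene length. Replicate numbers are shared by the labels of all groups, which do not say what a number stands for. They were taken to pair the samples only for the CG7818 and double depletions, where the correlations of same-numbered libraries' deviations were 0.192, 0.109 and 0.156. In every other pair of groups at least 1 of the 3 correlations was 0.1 or lower. For the paired comparison the alternatives added after the data were seen were also run together with the block. Permutation tests over genes used 100000 permutations, or 20000 within deciles of exon length. They treat genes as independent and leave out the spread between libraries, so only the differences of medians are given. Summaries and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.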

Results

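Poly(A) RNA was sequenced from S2R+ cells, a macrophage-like line derived from Drosophila melanogaster embryos, in 7 groups of 3 libraries each. Besides the control, the groups were depletions of Ime4, of CG7818, of both (the double depletion), of Fl2d, of CG6422 and of YT521. Ime4 (Mettl3) and CG7818 (Mettl14) are the subunits of the core that writes N6-methyladenosine (m6A) into mRNA, and Fl2d is a further protein of the writer complex. CG6422 (Ythdf) and YT521 (Ythdc1) are proteins of the YTH family, which bind m6A, the first of the cytoplasmic type and the second nuclear. The series title links m6A to neurogenesis, sex determination and the nuclear reader, so the comparisons ask which transcripts changed when a writer or a reader was depleted. Counts assigned to genes ranged from 20214568 to 28296393 per library, with a median of 22126193, and 10543 to 10963 genes had a count. After the filter on low counts 8360 genes were tested. Levels are given in counts-per-million (CPM), mean ± SD over 3 libraries, and changes as log2 fold changes with their standard error (SE). Adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over these 8360 genes, and a gene is said to have risen or fallen where that value was under 0.05. The labels do not say that replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical. The first principal component took 27.2% of the variance and set the Fl2d libraries, at 33.8, 21.1 and 22.6, apart from all others, which lay between −11.0 and −1.04. A pair of libraries stood apart in the mitochondrial large ribosomal RNA, mt:lrRNA. It made up 1.93% of gene counts in Fl2d replicate 1 and 2.89% in YT521 replicate 2, against 5.61% to 8.62% in the other libraries. Since the strand setting of the counting is not given in the sources used here, the values of genes that overlap another gene are uncertain. Of the genes named here these are Mettl14, Ythdf, SkpB, AGO1, brat, Alp4, Pcyt2, CG7916, drpr, Ire1, CG33127, spn-E, Hrb98DE, RpL7A, Sxl, Lip3, rpk, Phb2, Gel, CG13654, CG9503, Obp44a, axo, sli, unc-5, caps, fok, bgcn, mira, Rbp9, Diap1, p53, Prp31, Clamp, NimC4, RpLP0-like, RpS5a, key, spz, Rel, Mcm7, Tig, cher, robo2, Syx1A, CG4269, Tusp, Mmp1, mael, Ten-m, Dscam1, Nrg, Fas3, AGO2, Dcr-2, Not1, ND-15, Nt5b, CG4793, CG17930 and Cyp6d2. Reads can also be shared between near-identical copies, which bears on GstD2, the Hsp70 genes, RpS5a, RpS5b, RpS19b and COX7AL.

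Each targeted transcript was low in every library labelled as its depletion. Mettl3 (FBgn0039139, chromosome 3R, 24032157 to 24034257, plus strand, build BDGP6.54) stood at 61.6 ± 1.5 CPM in the control. It was at 5.76 ± 0.72 CPM in the Ime4 depletion (9.35% of the control, log2 fold change −3.41, SE 0.146, adjusted p = 1.02e-12) and at 5.33 ± 2.6 CPM in the double depletion (8.66%, −3.51, adjusted p = 3.71e-13). Mettl14 (FBgn0032016, chromosome 2L, 8308427 to 8309961, plus strand) fell from 64.5 ± 1.4 CPM to 5.80 ± 1.0 CPM in the CG7818 depletion (8.98%, −3.48, SE 0.109, adjusted p = 1.47e-15) and to 6.18 ± 1.6 CPM in the double depletion (9.57%, −3.37, adjusted p = 2.17e-15). The transcript of fl(2)d (FBgn0000662, chromosome 2R, 13819624 to 13824553, minus strand) fell from 125 ± 1.6 to 21.7 ± 3.1 CPM in its own depletion (17.3%, −2.53, SE 0.073, adjusted p = 2.71e-16). Ythdc1 (FBgn0027616, chromosome 3L, 3370451 to 3374170, minus strand) fell from 391 ± 15 to 86.7 ± 15 CPM in the YT521 depletion (22.2%, −2.17, SE 0.084, adjusted p = 1.07e-13). Ythdf (FBgn0039261, chromosome 3R, 25033876 to 25039249, minus strand) fell from 98.2 ± 7.0 to 25.3 ± 7.0 CPM in the CG6422 depletion (25.8%, −1.95, SE 0.121, adjusted p = 1.88e-09).

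**Figure D1:**
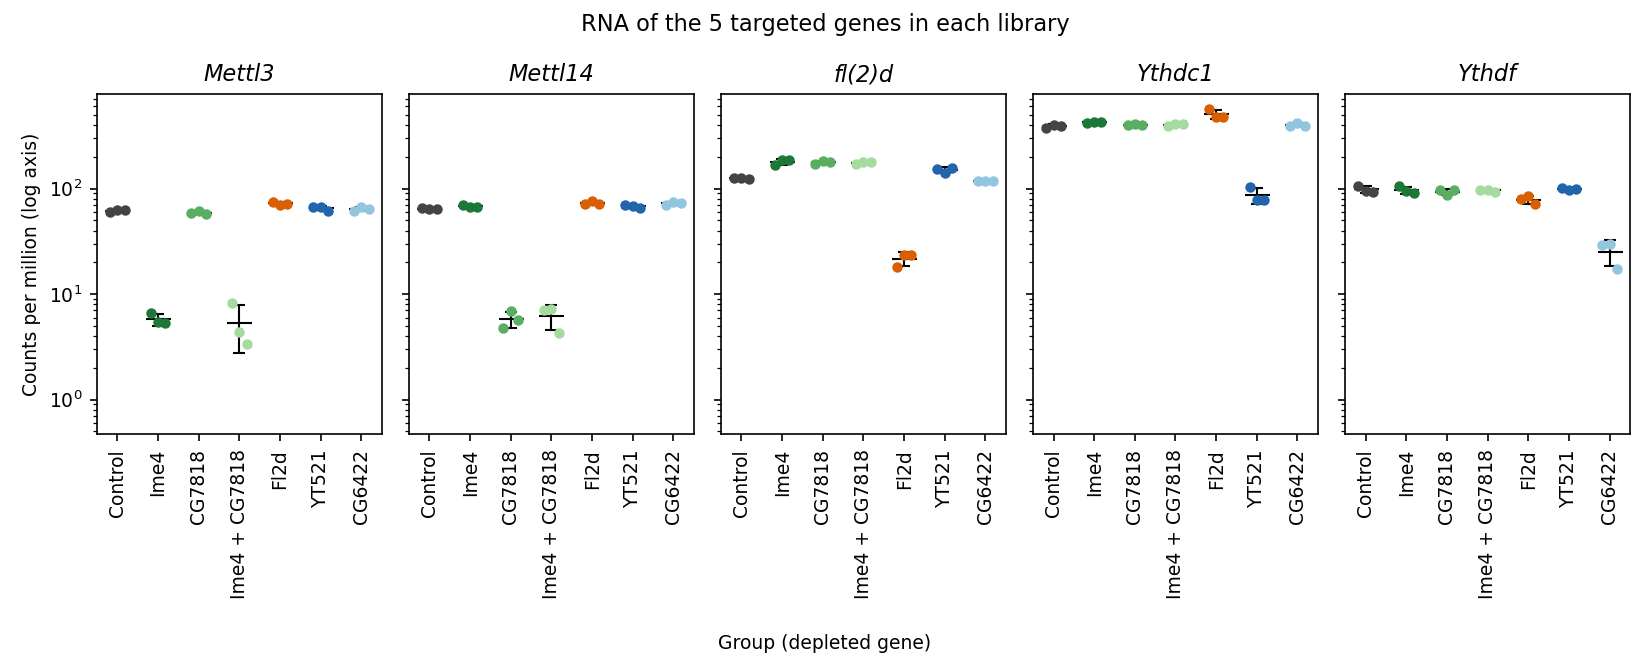
RNA of the 5 targeted genes in CPM (log axis) for each of the 7 groups: points are single libraries, the horizontal mark is the mean of 3 libraries and the bar its SD. Each transcript is low in the depletions named for it, for example Mettl3 at 5.76 CPM in the Ime4 group against 61.6 CPM in the control.

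Depleting one component was followed by changes in the RNA of others. The transcript of fl(2)d rose in the Ime4 depletion to 180 ± 11.6 CPM (log2 fold change 0.52, SE 0.064, adjusted p = 3.78e-05), in the CG7818 depletion to 178 ± 4.7 CPM (0.50, adjusted p = 6.83e-05) and in the double depletion to 176 ± 4.3 CPM (0.49, adjusted p = 3.31e-05). It also rose in the YT521 depletion, to 151 ± 8.7 CPM (0.27, adjusted p = 0.0139). That last call was lost without YT521 replicate 1 (adjusted p = 0.0701), YT521 replicate 3 (0.0575), Control replicate 2 (0.0518) or Control replicate 3 (0.0569), within a range of 1.18e-04 to 0.0701 over its alternatives. In the CG6422 depletion fl(2)d was at 117 ± 0.37 CPM (−0.10, adjusted p = 0.329). Tested directly, fl(2)d was higher in the Ime4 than in the CG6422 depletion by 0.62 (adjusted p = 7.09e-06), and higher in the YT521 than in the CG6422 depletion by 0.36 (6.08e-04). It was also higher in the Ime4 than in the YT521 depletion, by 0.26 (0.016). In the Fl2d depletion Ythdc1 rose to 507 ± 53 CPM (0.38, adjusted p = 7.07e-04). Ythdf fell there to 78.7 ± 6.7 CPM (−0.32, adjusted p = 0.0279), a call that was lost without Fl2d replicate 3 (0.0921), without Control replicate 1 (0.118) and with a gene length correction (0.0519), within a range of 1.57e-04 to 0.118. Mettl3 and Mettl14 passed the test in no depletion that did not target them, with Mettl3 at 59.1 to 72.3 CPM (adjusted p = 0.112 to 0.874) and Mettl14 at 67.8 to 73.0 CPM (0.0967 to 0.730).

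Under depletion of Ime4 several of the larger changes were in lowly expressed genes. SkpB, a Skp1-type ubiquitin ligase component, rose from 0.666 ± 0.063 to 1.502 ± 0.17 CPM (log2 fold change 1.16, SE 0.208, adjusted p = 0.00255), and Pcyt2 fell from 3.48 ± 0.25 to 1.54 ± 0.27 CPM (−1.19, SE 0.216, adjusted p = 0.00291). CG15784 rose from 311 ± 52 to 622 ± 47 CPM (1.0, SE 0.101, adjusted p = 3.56e-06), with CG31029 at 0.99 and CG10062 at 0.95. The non-coding RNA CR45517 fell by 1.08 and CG7916 by 0.99. Among moderately expressed genes, the engulfment receptor gene drpr rose from 101 ± 2.4 to 134 ± 6.3 CPM (0.41, adjusted p = 4.18e-06). The papilin gene Ppn, which encodes an extracellular matrix protein, rose from 12.3 ± 0.86 to 16.9 ± 1.2 CPM (0.45, adjusted p = 7.82e-04), and the Hsp90 co-chaperone gene Stip1 from 315 ± 7.7 to 388 ± 7.9 CPM. In all, 148 genes rose and 163 fell, 3.72% of those tested, with a median absolute log2 fold change of 0.32. Of the 311, 13 changed at least 2-fold and 309 had 3 libraries per group without overlap, which chance gives for 10% of genes and which held for 27.5% of all genes. Leaving out a library gave 151, 151 or 197 calls without Ime4 replicate 1, 2 or 3, and 194, 142 or 184 without Control replicate 1, 2 or 3.

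Of the gene lists tested, 5 moved with Ime4 depletion. In the extracellular matrix, integrin and cytoskeleton list 1 of 37 members rose and 4 fell, 1 and 7 adjusted over the list alone. The laminin gene LanB1 fell from 147 ± 6.3 to 101 ± 2.0 CPM (−0.54, SE 0.054, adjusted p = 3.56e-06). The list was lower than other genes by camera (adjusted p = 0.00269), with adjusted p = 0.17 with an estimated correlation, within 0.00241 to 0.17 over its alternatives. Of 22 innate immune genes 4 fell and 0 rose, as they did adjusted over the list alone, among them dl, an NF-kappa-B factor of the Toll pathway, from 71.7 ± 2.8 to 59.4 ± 1.1 CPM (−0.27, adjusted p = 0.00328). That list was lower by camera (0.00153) and stayed under 0.05 with adjusted p = 0.0303 with an estimated correlation, within 4.15e-05 to 0.0303. Of 22 genes of the unfolded protein and integrated stress responses 4 rose and 0 fell, 5 and 1 adjusted over the list alone. The ATF4 homologue crc rose from 668 ± 25 to 907 ± 43 CPM (0.44, SE 0.061, adjusted p = 1.42e-04) and Sil1, a nucleotide exchange factor of the endoplasmic reticulum, by 0.23. The stress list was higher by camera (0.0308), with adjusted p = 0.414 with an estimated correlation, within 0.00703 to 0.414. Its call was also lost without Ime4 replicate 2 (0.0567), Ime4 replicate 3 (0.113), Control replicate 1 (0.0622) or Control replicate 2 (0.126). The 10 crystal cell and lamellocyte markers were lower (camera adjusted p = 0.0151; adjusted p = 0.17 with an estimated correlation; range 0.0026 to 0.17), with 1 member fallen in either adjustment, and lost the call without Ime4 replicate 1 (0.0586). The 82 cytosolic ribosomal protein genes were lower (0.00136; adjusted p = 0.809 with an estimated correlation; range 1.11e-06 to 0.809), although 1 rose and only 2 fell in either adjustment, and lost the call without Control replicate 3 (0.157).

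Depletion of CG7818 gave the smallest count of the 6 depletions, 92 genes higher and 102 lower, or 2.32% of those tested. CG33127 rose from 0.959 ± 0.043 to 2.36 ± 0.35 CPM (1.29, SE 0.177, adjusted p = 1.58e-04). CG2961 rose by 1.20 and Smyd4-2 by 1.16, and CG15784 rose to 708 ± 60 CPM (1.19, adjusted p = 1.44e-07). The receptor gene drpr rose to 144 ± 3.4 CPM (0.51, SE 0.042, adjusted p = 8.59e-08), Ppn by 0.56, and spn-E, a helicase of the piRNA pathway, by 0.45. CG14694 fell from 1.29 ± 0.19 to 0.309 ± 0.063 CPM (−2.02, SE 0.271, adjusted p = 1.14e-04). Hrb98DE, an hnRNP A-type RNA-binding protein, fell from 286 ± 12 to 174 ± 4.4 CPM (−0.71, SE 0.054, adjusted p = 2.60e-08), and RpL7A, a ribosomal protein gene, from 2994 ± 172 to 1915 ± 126 CPM (−0.65, SE 0.085, adjusted p = 8.84e-05). Hrb87F, of the same hnRNP class, rose by 0.21. Hsp70Bbb fell by 1.17 and CR45517 by 1.14. Of 22 stress response genes 3 rose and 0 fell, 6 and 0 adjusted over the list alone, with camera adjusted p = 0.0162 and adjusted p = 0.319 with an estimated correlation, within 0.00369 to 0.319. That call was lost without CG7818 replicate 3 (0.0583) or Control replicate 2 (0.101). The list of the writer complex and readers holds the targeted genes, so it is not independent evidence. Of its 9 members 1 rose, fl(2)d, and 1 fell, Mettl14 (camera adjusted p = 1.83e-08; adjusted p = 0.00569 with an estimated correlation; range 5.58e-09 to 0.00569). The sex determination gene Sxl fell by 0.57, a call that was lost without CG7818 replicate 1 (adjusted p = 0.0825), CG7818 replicate 2 (0.0893), Control replicate 1 (0.0732) or Control replicate 2 (0.0646), within 1.19e-04 to 0.0893. All 194 called genes had groups without overlap, against 22.8% of all genes and 10% by chance. The median absolute log2 fold change of the called genes was 0.39, and 17 changed at least 2-fold. The count was 107, 111 or 101 without CG7818 replicate 1, 2 or 3, and 105, 95 or 122 without Control replicate 1, 2 or 3.

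In the double depletion part of the genes of the unfolded protein and integrated stress responses rose. The chaperone gene Hsc70-3 (BiP) rose from 2199 ± 116 to 2926 ± 45 CPM (log2 fold change 0.41), the stress sensor Ire1 from 127 ± 8.4 to 165 ± 2.6 CPM (0.38), and crc from 668 ± 25 to 1045 ± 32 CPM (0.65, SE 0.061, adjusted p = 4.07e-07). Sil1 rose to 100 ± 1.5 CPM (0.35). Of the 22 genes of this list 6 rose and 0 fell, 9 and 1 adjusted over the list alone, with camera adjusted p = 6.39e-06 and adjusted p = 0.0463 with an estimated correlation, within 3.82e-07 to 0.0463 over its alternatives. In the matrix and cytoskeleton list 1 of 37 members rose and 10 fell, 1 and 15 adjusted over the list alone. LanB1 fell to 97.7 ± 2.6 CPM (−0.59, adjusted p = 2.88e-07), LanB2 from 209 ± 11 to 169 ± 6.6 CPM (−0.31), and Tig, which encodes an integrin ligand, from 135 ± 9.9 to 98.3 ± 5.9 CPM (−0.46). The camera adjusted p was 1.62e-04, with adjusted p = 0.0636 with an estimated correlation, within 4.15e-05 to 0.0636. Of 45 genes of the cell cycle and DNA replication 0 rose and 12 fell, 1 and 16 adjusted over the list alone. The replicative helicase gene Mcm7 fell from 91.1 ± 4.4 to 75.3 ± 2.9 CPM (−0.28), Mcm5 by 0.22 and RnrS, a subunit of ribonucleotide reductase, by 0.19. Camera gave an adjusted p of 1.86e-04 for this list, with adjusted p = 0.319 with an estimated correlation, within 4.58e-05 to 0.319. Of the 9 writer and reader genes, which include both targets, 1 rose and 2 fell (3.1e-18; adjusted p = 1.99e-04 with an estimated correlation; range 6.36e-31 to 1.99e-04).

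The double depletion changed 955 genes, 526 higher and 429 lower, or 11.4% of those tested. GstD2, a glutathione S-transferase, rose from 1.20 ± 0.21 to 4.09 ± 0.16 CPM (1.76, SE 0.180, adjusted p = 1.17e-06), the alkaline phosphatase gene Alp4 by 1.51, the lipase gene Lip3 by 1.40, SkpB by 1.39, the sodium channel gene rpk by 1.35, CG10814 by 1.34 and CG15784 by 1.31, to 770 ± 55 CPM. Pcyt2 fell by 1.25, the acyl-CoA synthetase gene bgm by 1.24, CG14694 by 1.18, CR45517 by 1.17 and CG1544 by 1.15. Of genes outside these extremes, pirk, a negative regulator of immune signalling, rose by 0.51, p53 by 0.36, bgcn by 0.78 and drpr by 0.49. The Toll ligand gene spz fell by 0.50, dl by 0.28, key by 0.22, the guidance receptor gene robo2 by 0.53, Syx1A by 0.34, Hrb98DE by 0.56 and RpL7A by 0.46. The median absolute log2 fold change was 0.30, and 69 genes changed at least 2-fold. Groups did not overlap for 951 of the 955, against 34.8% of all genes and 10% by chance. The count was 533 without replicate 1 of the double depletion, 590 without its replicate 2 and 461 without Control replicate 2, and 698 to 752 without each of the other libraries.

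**Figure D2:**
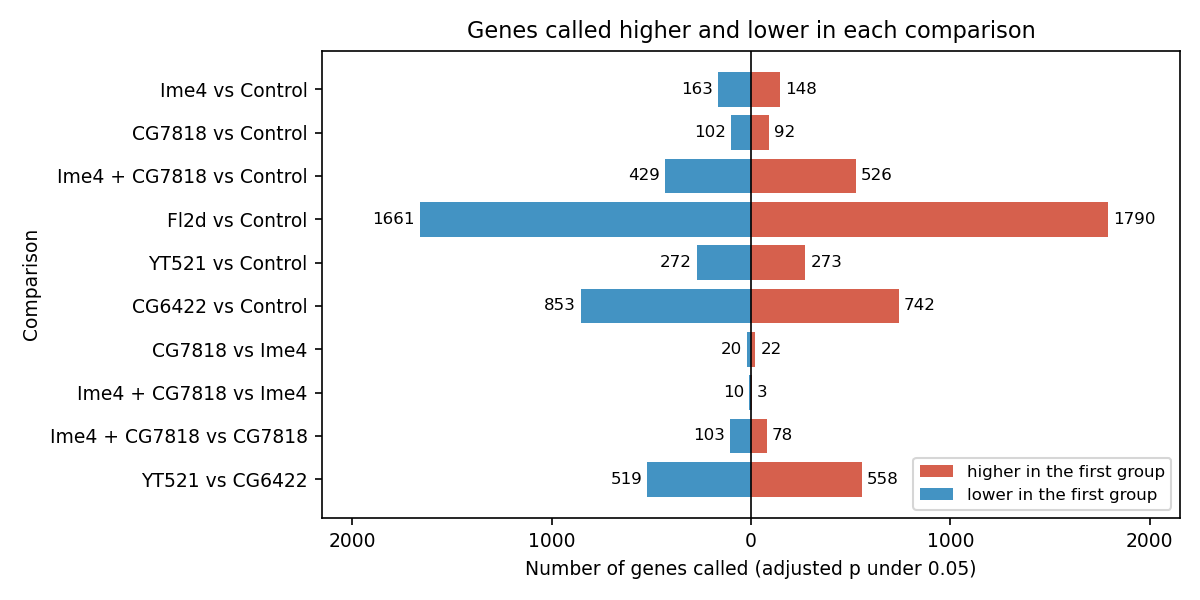
Number of genes called higher (right) and lower (left) in the first group of each comparison, at an adjusted p under 0.05 in edgeR's quasi-likelihood test with 3 libraries per group. The Fl2d depletion has the longest bars, 1790 higher and 1661 lower, and the double depletion against the Ime4 depletion the shortest, 3 higher and 10 lower.

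Depletion of Fl2d gave the largest count, 1790 genes higher and 1661 lower, or 41.3% of those tested. CG15784 rose to 3617 ± 228 CPM (log2 fold change 3.54, SE 0.110, adjusted p = 6.62e-16), CG33127 by 2.61, Alp4 by 2.27, CG14545 by 2.19 and the transcription factor gene bab1 by 2.08. CG13654 fell from 16.1 ± 1.2 to 2.85 ± 0.12 CPM (−2.49), axo from 20.7 ± 1.1 to 4.08 ± 0.26 CPM (−2.34), CG1544 by 2.78, CG9503 by 2.41 and the odorant-binding protein gene Obp44a by 2.35. Among single genes of the axon guidance and neural fate lists some rose and others fell. The guidance ligand gene sli rose from 49.4 ± 5.0 to 119 ± 9.8 CPM (1.26, SE 0.095, adjusted p = 1.70e-09), mira, which encodes a neuroblast adaptor protein, by 1.84, brat by 0.30 and the neuronal RNA-binding protein gene Rbp9 from 5.46 ± 0.40 to 10.1 ± 0.78 CPM (0.89). Of these, mira was lowly expressed, at 0.385 ± 0.067 CPM in the control, so its value rests on few counts. The netrin receptor gene unc-5 fell from 66.5 ± 5.8 to 41.1 ± 2.1 CPM (−0.69), tutl by 0.96 and caps by 0.62. Of 27 axon guidance and adhesion genes 1 rose and 13 fell in either adjustment, with camera adjusted p = 0.0134 and adjusted p = 0.637 with an estimated correlation, within 0.00373 to 0.637. That call was lost without Fl2d replicate 1 (0.0608), one of the libraries low in mt:lrRNA, without both low libraries (0.0710) and with the gene length correction (0.152). Of the sex determination and dosage compensation list, which has 16 members, 1 rose and 6 fell in either adjustment, with camera adjusted p = 0.204. Sxl, the master switch of sex determination, fell from 11.4 ± 0.34 to 7.48 ± 1.6 CPM (−0.61, SE 0.132, adjusted p = 9.68e-04), its co-repressor gene Unr from 137 ± 15 to 91.2 ± 14 CPM (−0.58) and Clamp by 0.19, while fru rose from 67.9 ± 2.5 to 82.3 ± 5.5 CPM (0.28). Counts per gene do not show how a transcript was spliced, so the splicing of Sxl and fru was not tested.

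Of 21 apoptosis and p53 target genes 9 rose and 2 fell in either adjustment. The caspase gene Drice rose from 140 ± 0.50 to 191 ± 1.5 CPM (0.45), the caspase inhibitor gene Diap1 from 273 ± 6.6 to 351 ± 4.4 CPM (0.36), p53 from 22.7 ± 0.44 to 32.2 ± 1.7 CPM (0.50) and the TNF receptor gene wgn by 0.49. Camera gave an adjusted p of 0.0128 for them, with adjusted p = 0.0728 with an estimated correlation, within 3.13e-08 to 0.0728. Of the 82 cytosolic ribosomal protein genes 30 rose and 0 fell, 20 and 0 adjusted over the list alone. RpS5b rose from 1.30 ± 0.16 to 4.08 ± 0.77 CPM (1.66), RpS19b by 0.60, RpLP0-like by 0.47 and RpS5a by 0.39. Camera gave 0.00136, with adjusted p = 0.809 with an estimated correlation, within 1.28e-05 to 0.809. Further single genes that fell were Thor, a repressor of translation initiation, from 61.7 ± 9.7 to 29.7 ± 4.7 CPM (−1.05), the lactate dehydrogenase gene Ldh from 709 ± 138 to 412 ± 78 CPM (−0.78), CecA1, an antimicrobial peptide gene (−1.02), fok (−2.14), Hsp70Ba (−2.17), and AGO1, an Argonaute gene (−0.51). The receptor gene drpr rose to 192 ± 3.7 CPM (0.93), SPARC by 0.64, the integrin gene mys by 0.43, bgcn by 1.57, spn-E by 0.67 and the splicing factor gene Prp31 by 0.51. The median absolute log2 fold change was 0.33 and 314 genes changed at least 2-fold. Groups did not overlap for 3109 of the 3451, against 45.8% of all genes and 10% by chance. Without each of the 6 libraries in turn 2789 to 3450 genes were called, the fewest without Fl2d replicate 1. With only the 2 compared groups fitted the count was 2221, against 1646 in the CG6422 and 1616 in the double depletion.

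In the YT521 depletion drpr was the clearest change besides the target. It doubled from 101 ± 2.4 to 203 ± 6.0 CPM (log2 fold change 1.003, SE 0.042, adjusted p = 3.39e-13). The potassium channel gene eag rose from 6.68 ± 0.73 to 13.5 ± 0.47 CPM (1.03), Tusp from 4.16 ± 0.98 to 9.17 ± 1.4 CPM (1.17), CG2961 by 1.29 (SE 0.207, adjusted p = 5.22e-04), GstD2 by 1.27 and CG4269 by 1.23. NimC4, another receptor for apoptotic cells, rose from 15.6 ± 1.4 to 22.0 ± 1.1 CPM (0.49), the matrix metalloprotease gene Mmp1 by 0.58, pirk by 0.54 and Drice by 0.35. The piRNA pathway gene mael fell from 67.4 ± 2.7 to 42.1 ± 1.5 CPM (−0.68, SE 0.048, adjusted p = 6.11e-09), RpS19b from 93.1 ± 7.1 to 63.9 ± 4.8 CPM (−0.54), the carbonic anhydrase gene CAH7 from 35.8 ± 8.3 to 17.3 ± 3.2 CPM (−1.05), Lst by 1.21 and Pcyt2 by 1.09. In the matrix and cytoskeleton list 0 of 37 members rose and 8 fell, 0 and 11 adjusted over the list alone. LanB2 fell to 158 ± 9.9 CPM (−0.40), LanB1 to 120 ± 3.9 CPM (−0.28) and Tig by 0.40. Camera gave an adjusted p of 0.00567, with adjusted p = 0.196 with an estimated correlation and 0.0597 with the gene length correction, within 0.00204 to 0.196. Of 27 axon guidance genes 1 rose and 6 fell, 3 and 8 adjusted over the list alone. The receptor gene unc-5 fell by 0.41 and the teneurin gene Ten-m by 0.40. Camera gave 0.0490, with adjusted p = 0.746 with an estimated correlation, within 0.0114 to 0.746. The call was lost without YT521 replicate 1 (0.144), YT521 replicate 2 (0.153) or Control replicate 1 (0.192), and with DESeq2's size factors (0.0509), the mt:lrRNA covariate (0.178), both low libraries left out (0.1) and the gene length correction (0.458). Outside the called lists N, the Notch receptor gene, fell by 0.32 and Syx1A by 0.43. Sxl fell by 0.49, a call that was lost without YT521 replicate 2 (adjusted p = 0.111), Control replicate 1 (0.066) or Control replicate 2 (0.0691) and without both libraries low in mt:lrRNA (0.0509), within 5.67e-04 to 0.111.

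The remaining lists called in the YT521 depletion rested on few called members. Of 70 respiratory chain genes 2 rose and 0 fell, 1 and 0 adjusted over the list alone (camera adjusted p = 0.00269; adjusted p = 0.809 with an estimated correlation; range 2.33e-04 to 0.809). Of 82 ribosomal protein genes 1 rose and 1 fell, 0 and 1 adjusted over the list alone, with the list higher by camera (0.0258; adjusted p = 0.843 with an estimated correlation; range 2.43e-04 to 0.876). YT521 replicate 2 is the library of this group with the low mt:lrRNA share. Without it the respiratory chain list was at 0.133 and the ribosomal protein list at 0.515, and with the mt:lrRNA share as a covariate at 0.153 and 0.325. The respiratory list also lost its call without Control replicate 1 (0.102), and the ribosomal list without Control replicate 1 (0.380) or Control replicate 2 (0.0596). Of 45 cell cycle genes 0 rose and 1 fell, 0 and 0 adjusted over the list alone (0.0230; adjusted p = 0.637 with an estimated correlation; range 0.00762 to 0.637), with the call lost without YT521 replicate 1 (0.0912) or Control replicate 2 (0.126). Of 18 germline and follicle cell markers 0 rose and 2 fell in either adjustment (0.0269; adjusted p = 0.587 with an estimated correlation; range 0.00486 to 0.587), with the call lost without Control replicate 1 (0.123). Of the 9 writer and reader genes, which include the target, 2 rose and 1 fell. Their median change was 0.08 and their mean −0.16, with the test downward (0.0364; adjusted p = 0.319 with an estimated correlation; range 0.00101 to 0.319), and the call was lost without YT521 replicate 3 (0.0569). In all, 273 genes rose and 272 fell, 6.52% of those tested, with a median absolute log2 fold change of 0.33 and 35 changed at least 2-fold. Groups did not overlap for 543 of the 545, against 27% of all genes and 10% by chance. The count was 298 and 330 without YT521 replicate 1 and 2, 248 and 328 without Control replicate 2 and 3, and 495 and 379 without YT521 replicate 3 and Control replicate 1.

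In the CG6422 depletion AGO2, the Argonaute of the small interfering RNA pathway, fell from 334 ± 9.2 to 209 ± 11 CPM (log2 fold change −0.68, SE 0.079, adjusted p = 1.65e-05) and Dcr-2, its Dicer, from 70.1 ± 2.9 to 52 ± 2.8 CPM (−0.43). Of 21 genes of RNA interference and antiviral defence 1 rose and 7 fell in either adjustment, with camera adjusted p = 0.00698 and adjusted p = 0.17 with an estimated correlation and 0.0782 with the gene length correction, within 3.17e-04 to 0.17. Of 22 innate immune genes 1 rose and 10 fell, 1 and 11 adjusted over the list alone. The Toll receptor gene Tl fell from 40.8 ± 1.5 to 28.9 ± 4.1 CPM (−0.51), dl by 0.32, Rel, the NF-kappa-B factor of the Imd pathway, by 0.27 and key by 0.23. Their camera adjusted p was 0.00136, with adjusted p = 0.0303 with an estimated correlation, within 1.99e-06 to 0.0303. Of 27 axon guidance and adhesion genes 0 rose and 11 fell, 0 and 12 adjusted over the list alone. Dscam1 fell from 96.1 ± 2.1 to 61.4 ± 3.9 CPM (−0.65), the neuroglian gene Nrg by 0.76 and Fas3 by 1.05. Camera gave 7.56e-04, with adjusted p = 0.476 with an estimated correlation and 0.152 with the gene length correction, within 1.37e-04 to 0.476. Of 37 matrix and cytoskeleton genes 0 rose and 11 fell in either adjustment, among them the laminin gene LanA, from 467 ± 25 to 305 ± 34 CPM (−0.62), and cher, which encodes filamin, by 0.39 (camera adjusted p = 0.00389; adjusted p = 0.182 with an estimated correlation; range 2.87e-04 to 0.182). Of 19 plasmatocyte markers, the macrophage-like blood cell type, 1 rose and 8 fell, 1 and 9 adjusted over the list alone (0.00567; adjusted p = 0.507 with an estimated correlation and 0.0782 with the length correction; range 0.00148 to 0.507). Of 10 crystal cell and lamellocyte markers 0 rose and 4 fell, 0 and 6 adjusted over the list alone (0.00187; adjusted p = 0.0636 with an estimated correlation; range 4.15e-05 to 0.0636). Of 5 fat body and gut markers 3 fell in either adjustment (0.0229; adjusted p = 0.414 with an estimated correlation and 0.0782 with the length correction; range 0.00401 to 0.414), with the call also lost without Control replicate 2 (0.0547).

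Higher in the CG6422 depletion were rpk (1.47, SE 0.296, adjusted p = 0.00202), the cytochrome oxidase gene COX7AL (1.53), CG14545 (1.31), Lip3 (1.30), Alp4 (1.25), CG10062 (1.14), GstD2 (1.12) and SkpB (1.12). RpS19b rose to 142 ± 8.8 CPM (0.61), in the direction opposite to its fall in the YT521 depletion, and crc to 932 ± 33 CPM (0.48). Of 70 respiratory chain genes 11 rose and 0 fell, 10 and 0 adjusted over the list alone, among them the complex I genes ND-15 and ND-ACP, each by 0.23. Camera gave an adjusted p of 0.00140, with adjusted p = 0.809 with an estimated correlation and 0.606 with the gene length correction, within 1.64e-05 to 0.809. Besides the target, the lowest log2 fold changes among called genes with a mean of at least 1 CPM and groups without overlap were those of Obp44a (−1.63, SE 0.222, adjusted p = 9.15e-05) and the adenylyl cyclase gene Ac78C (−1.34). Not1, the scaffold of the main deadenylase, fell by 0.57, Stat92E by 0.31 and Mmp1 by 0.47. In all, 742 genes rose and 853 fell, 19.1% of those tested, with a median absolute log2 fold change of 0.28 and 57 changed at least 2-fold. Groups did not overlap for 1559 of the 1595, against 37.2% of all genes and 10% by chance. The count was 864 without CG6422 replicate 2, 889 without Control replicate 2 and 1078 to 1429 without each other library.

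Changes went with the length of the exons. Across 8183 genes the Spearman correlation of log2 fold change with exon length was −0.37 in the CG6422, −0.292 in the YT521, −0.197 in the double, −0.16 in the Fl2d, −0.112 in the Ime4 and 0.021 in the CG7818 depletion. These correlations are across genes, which are not independent replicates. Per library, the correlation of its deviation from the mean of all libraries was 0.165 to 0.221 in the controls and −0.41 to −0.152 in the CG6422 libraries, with the lowest value in CG6422 replicate 2. It spread within groups as well, from −0.23 to 0.081 in the YT521 and from −0.155 to 0.133 in the double depletion. With a gene length correction chosen after the data were seen, 1178 genes were called in the CG6422 depletion, including 949 of the 1595. Of the 8 lists called in that depletion, the innate immune (adjusted p = 3.61e-04), crystal cell and lamellocyte (0.0432) and matrix (0.0494) lists were called with the correction. The axon guidance, respiratory chain, plasmatocyte, RNA interference and fat body lists were not, at 0.0782 to 0.606. The correction also gave calls that were not there without it. In the CG6422 depletion the ribosomal protein list was lower (adjusted p = 1.71e-07 against 0.208, within 1.71e-07 to 0.943 over its alternatives) and the neural fate list higher (0.0467 against 0.46, within 0.0467 to 0.816). Elsewhere these were the ribosomal protein list in the double depletion (lower, 0.00207 against 0.223, within 0.00207 to 0.943), the ecdysone list in the CG7818 depletion (lower, 0.0441 against 0.0845, within 0.00776 to 0.524) and the plasmatocyte list in the YT521 depletion (higher, 0.0432 against 0.140, within 0.0339 to 0.798). None of the 7 lists called in the YT521 depletion was called with it, at 0.0597 to 0.876, and the ribosomal protein list turned its direction there.

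**Figure D3:**
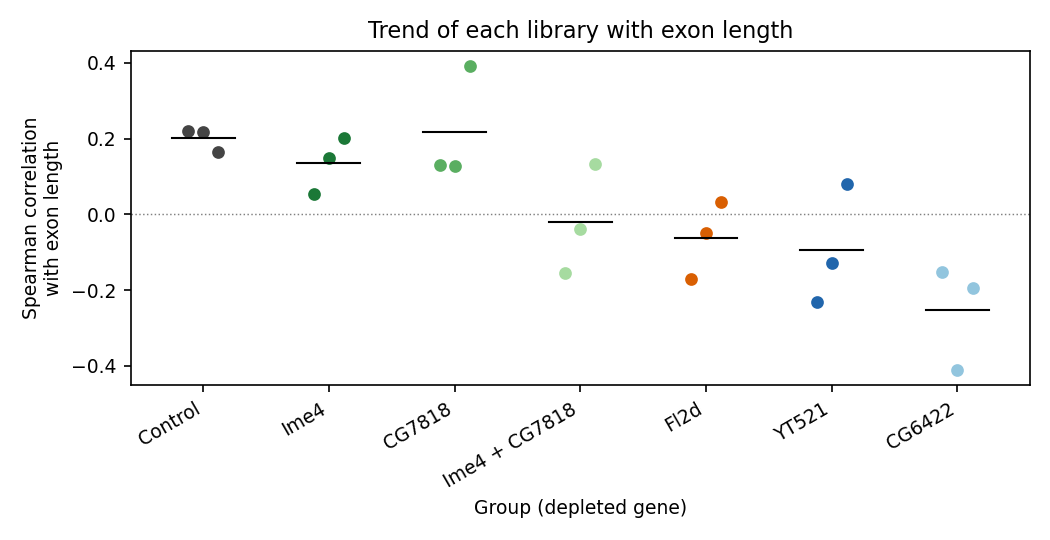
Spearman correlation, across 8183 genes, of each library's deviation from the mean log2 level with exon length; points are the 3 libraries of each group and the line is their mean. The controls lie at 0.165 to 0.221 and the CG6422 libraries at −0.41 to −0.152.

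The depletions of the writer core were compared with each other to ask whether they act alike. Between the CG7818 and Ime4 depletions 22 genes were higher and 20 lower, with the targets Mettl3 (3.35) and Mettl14 (−3.55) among them. LanB1 was at 150 ± 7.0 CPM under CG7818 and 101 ± 2.0 under Ime4 depletion (0.57, SE 0.054, adjusted p = 9.33e-07), and the nucleotidase gene Nt5b at 50.5 ± 0.42 against 93.7 ± 2.5 CPM (−0.89, SE 0.052, adjusted p = 1.60e-10). CG14694 was lower under CG7818 depletion (−1.93, adjusted p = 5.27e-04), as was CG31029 (−1.31, adjusted p = 7.58e-04). Other fits gave more genes, 46 with DESeq2's size factors, 64 with the replicate block and 67 with the gene length correction. DESeq2's Wald test gave 115, the mt:lrRNA covariate 178, and both libraries low in mt:lrRNA left out 223. With the Wald test 68.7% of the genes that differed were higher, against 52.4% here. Groups did not overlap for all 42 genes, against 24.2% of all genes and 10% by chance. The count was 17, 20 or 32 without Ime4 replicate 1, 2 or 3, and 25, 22 or 16 without CG7818 replicate 1, 2 or 3. Against the Ime4 depletion, the double depletion differed in 13 genes, 3 higher and 10 lower. RabX1, a gene of the Rab GTPase family, was at 67.1 ± 1.9 against 51.8 ± 1.3 CPM (0.37, adjusted p = 0.00288), meigo at 138 ± 4.3 against 107 ± 4.7 CPM (0.37, adjusted p = 0.00192), and Nt5b at 58.1 ± 2.4 against 93.7 ± 2.5 CPM (−0.69, adjusted p = 3.12e-08). The size factors gave 13 genes as well, the gene length correction 14 and the replicate block 22. Both libraries low in mt:lrRNA left out gave 33, the covariate 37 and DESeq2's Wald test 45. The small count thus depends on the fit. With the Wald test 51.1% of the differing genes were higher, against 23.1% here. The count was 7 without Ime4 replicate 1, 7, 6 or 8 without replicate 1, 2 or 3 of the double depletion, and 10 without Ime4 replicate 2 or 3. Against the CG7818 depletion, the double depletion differed in 181 genes, 78 higher and 103 lower. With the gene length correction 145 genes differed, 77 higher and 68 lower, and 123 of the 181 kept the call. The replicate block gave 258 genes, DESeq2's Wald test 299, the covariate 354 and both libraries low in mt:lrRNA left out 391. CG10814 was at 12.2 ± 0.48 against 5.55 ± 0.82 CPM (1.14, adjusted p = 0.00158), and LanB1 was lower (−0.62, adjusted p = 6.40e-07). The count was 55, 43 or 28 without CG7818 replicate 1, 2 or 3, and 26, 31 or 61 without replicate 1, 2 or 3 of the double depletion.

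The reader depletions differed from each other in 1077 genes, 558 higher and 519 lower under YT521 than under CG6422 depletion. Besides Ythdf (1.97) and Ythdc1 (−2.21), Obp44a was at 3.79 ± 0.55 against 0.959 ± 0.13 CPM (1.97, adjusted p = 1.46e-06) and CG4793 at 31.2 ± 2.8 against 9.54 ± 1.3 CPM (1.71, adjusted p = 3.58e-10). CG17930 was higher by 1.68, and rpk (−1.37) and the cytochrome P450 gene Cyp6d2 (−1.30) were lower. Of the 1077 genes 104 differed at least 2-fold, and the median absolute log2 difference was 0.31. Groups did not overlap for 1045 of them, against 28.4% of all genes and 10% by chance. Without CG6422 replicate 2 there were 679 calls, and 732 to 1017 without each other library.

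A small set of genes changed in one direction under every depletion. The 23 genes called in all 6 comparisons with the control in one direction, 12 up and 11 down, included the prohibitin gene Phb2 (0.48 in the Ime4, 0.40 in the CG7818, 0.69 in the double, 0.58 in the Fl2d, 0.41 in the YT521 and 0.51 in the CG6422 depletion). RabX1 rose by 0.34 to 0.97, meigo by 0.31 to 0.86, Stip1 by 0.22 to 0.48, and the aldehyde oxidase gene AOX1 by 0.28 to 1.27. The inhibitory Smad gene Dad changed by −1.57 to −0.56. Phb2 was at 272 ± 9.1 CPM in the control, 379 ± 7.4 in the Ime4 and 438 ± 16 in the double depletion. In the simulated data without changes 0 genes were called in all 6. A comparison called at most 3 genes there, so this 0 could hardly be otherwise. It is no chance value for the 23 genes, to which the shared controls may contribute. Across the 3 writer core depletions 99 genes were shared, 48 up and 51 down, and 43 of these, 22 up and 21 down, also moved the same way in the YT521 depletion. Of the 43, 37 moved the same way in the Fl2d depletion too, and 23 are the genes called in all 6. The 43 include drpr (0.41, 0.51, 0.49 and 1.003 in the Ime4, CG7818, double and YT521 depletions), CG15784 (1.0, 1.19, 1.31 and 0.68) and Gel, which encodes the actin-severing protein gelsolin (−0.40, −0.45, −0.67 and −0.47).

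Pairs of depletions shared calls far above what independent lists give. The Ime4 and CG7818 depletions shared 105 genes in one direction and 0 in opposite directions, against 3.62 for independent lists. The Ime4 and double depletions shared 254 against 17.7, and the CG7818 and double depletions 151 against 11. With the Fl2d depletion, Ime4 shared 259 against 64.1, CG7818 163 against 40 and the double 551 against 198. The YT521 depletion shared 92 with Ime4 against 10.1 and 55 with CG7818 against 6.32. It shared 172 with the double against 31.1, 247 with Fl2d against 112 and 211 with CG6422 against 52. The CG6422 depletion shared 212 with Ime4 against 29.8, 83 with CG7818 against 18.6, 518 with the double against 90.5 and 834 with Fl2d against 328. Called in opposite directions were 88 genes for Fl2d with CG6422, 78 for Fl2d with YT521, 55 for Fl2d with the double, 36 for YT521 with CG6422, 17 for YT521 with the double and 0 to 10 for each other pair. In simulated unchanged groups at most 1 gene was shared by a pair. A comparison called at most 3 genes there, so this is no chance value for the longer lists here. The correlation of log2 fold changes across genes ran from 0.306 (Fl2d with YT521) to 0.716 (Ime4 with the double), against 0.479 to 0.507 in simulated unchanged groups. It lay below its simulated value in every pair with the YT521 depletion and for CG6422 with CG7818 (0.420 against 0.488) and with Fl2d (0.463 against 0.479). The covariance exceeded its simulated value in all 15 pairs, by 0.0071 (CG7818 with YT521) to 0.0455 (the double with Fl2d), with 0.0173 for Ime4 with CG7818. The 3 control libraries cannot be split into a pair of groups of at least 2, so part of the excess may come from the shared controls. Shared calls were not counted with the gene length correction. How far the trend with exon length, which sets the controls apart from most depletions, adds to them was not tested.

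**Figure D4:**
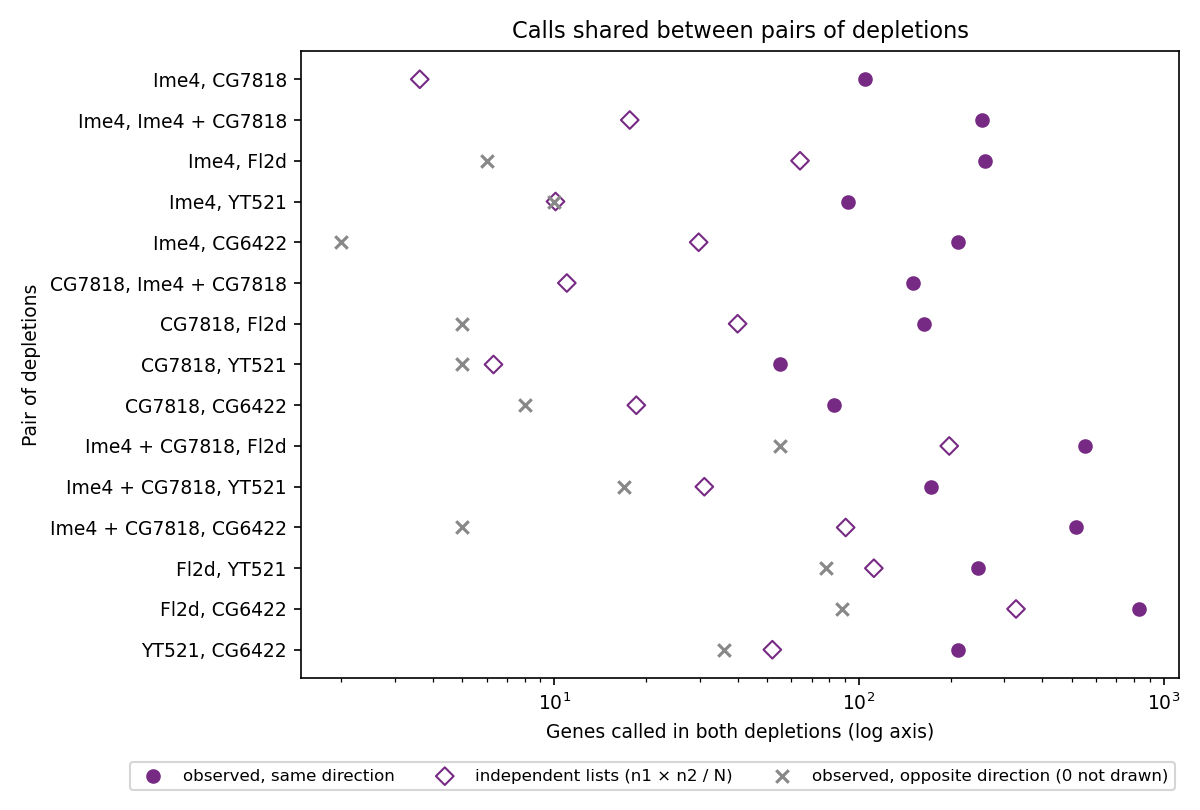
Genes called in both depletions of each pair (log axis): filled circles are genes changed in the same direction, diamonds the number for independent lists, and crosses genes changed in opposite directions. All 15 pairs lie above the independent value, for example 105 genes against 3.62 for Ime4 with CG7818.

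The other 11 lists gave no call by camera in any depletion as fitted here. Only 6 of the 26 matched neural fate genes passed the filter on low counts, so most of that list was not tested. For lists tied to the title of the series, the lowest adjusted p was 0.204 for sex determination and 0.30 for neural fate, both under Fl2d depletion, where 3 of the 6 neural fate genes rose and 0 fell in either adjustment. Of 12 synapse and excitability genes 3 rose and 3 fell there, 4 and 5 adjusted over the list alone, with a lowest adjusted p of 0.455 over the depletions. Of 41 splicing regulators 7 rose and 7 fell under Fl2d depletion, 6 and 6 adjusted over the list alone (lowest adjusted p 0.118, in the double depletion). Of 25 mRNA decay genes 7 rose and 4 fell in either adjustment (lowest 0.223, CG6422), and of 17 Notch pathway genes 2 rose and 3 fell in either adjustment (lowest 0.230, double). Of 20 heat shock and chaperone genes 3 rose and 9 fell under Fl2d depletion, 3 and 10 adjusted over the list alone (0.0946), and of 20 insulin and TOR genes 0 rose and 8 fell in either adjustment (0.0833). The insulin and TOR list was tested without InR, S6k and Tor, the Notch list without Dl and Psn, and the mRNA decay list without Dcp1 and Dcp2. These were not matched to a gene ID. Of 18 ecdysone response genes 5 rose and 4 fell (lowest 0.0845, CG7818), of 16 glycolysis genes 1 rose and 4 fell (lowest 0.110, double), and of 11 muscle markers 1 rose and 5 fell (lowest 0.0845, CG6422), the counts under Fl2d depletion and the same adjusted over the list alone. The writer and reader list was at 0.140, 0.145 and 0.159 in the Ime4, Fl2d and CG6422 depletions. Of the 150 list tests 29 were called with the preset correlation and 5 with an estimated one, which were the innate immune list in the Ime4 and CG6422 depletions, the stress response list in the double depletion, and the writer and reader list in the CG7818 and double depletions. The writer and reader list holds the targeted genes, so its calls are not independent evidence. Of the 496 named gene values that passed the test 329 kept the call in every alternative run and 167 lost it in at least 1.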

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

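The tests on fl(2)d and the gene length correction in the Fl2d depletion were chosen only after the results were seen. The mt:lrRNA covariate was likewise added after the data were seen. The share of reads aligned to several places, which enters no comparison, was higher in all 3 libraries of a depletion than in all 3 controls (mean 12.97% ± 0.749, range 12.14% to 13.6%) in 3 of the 6 depletions. It was 16.4% ± 0.996 in the Ime4 libraries (15.86% to 17.59%), 16.3% ± 0.55 in the double depletion (15.87% to 16.92%) and 14.9% ± 1.03 in the CG6422 libraries (13.83% to 15.86%). Each had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries can give. In the CG7818, Fl2d and YT521 depletions the exact p was 0.3, 0.4 and 0.8.

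For each of the 10 comparisons, 1 of the 10 splits of its 6 libraries called as many genes as the real one, which was the real one itself, and the highest other split called 0. With 10 splits no share under 0.05 can be reached. Every other split mixed libraries of both groups, which puts the difference between them into the spread within groups. The 0 calls there could thus hardly be otherwise and are no chance value for the real counts. In the double against the CG7818 depletion, whose replicate numbers were taken to pair the samples, the 10 splits include those that part as many pairs. The real counts were 311, 194, 955, 3451, 545 and 1595 for the Ime4, CG7818, double, Fl2d, YT521 and CG6422 depletions. They were 42, 13 and 181 within the writer core (CG7818 against Ime4, the double against Ime4 and against CG7818) and 1077 between the readers.

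The transcript of fl(2)d was higher in the Ime4, CG7818 and double depletions. The scaling of the libraries alone, which moves all genes alike, is argued against, since fl(2)d rose by 0.49 to 0.52 above the median of all genes, at least 7.67 times its SE. Spill-over of reads from the neighbours stj and CG13339 is argued against by their median log2 change of 0.03, and a single library by a lowest ratio of 6.43 with 1 library left out (3.24 for the smaller rise in the YT521 depletion, whose call was lost without some libraries at adjusted p up to 0.0701, within 1.18e-04 to 0.0701). An effect of any depletion whatever its target is argued against by the difference between the Ime4 and CG6422 depletions, 9.61 times its SE. A response of fl(2)d RNA to loss of the writer core may remain as a hypothesis found and tested on the same data, and whether it runs through the mark or through stability of the complex was not tested.

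Genes with more than 20 kb outside exons were lower in the CG6422 depletion, by a difference of medians of −0.137 on the log2 scale against the other genes. A single library is argued against, since the difference nearest to 0 with 1 library left out was −0.079. The trend with exon length is a candidate explanation, since within deciles of exon length the difference was −0.009. The length trend itself differed between libraries of one group, so a technical origin of it and an effect of the depletion stay open.

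The Fl2d depletion called 3451 genes, against 1595 in the CG6422 depletion, the next largest count. The gap was smaller with only the 2 compared groups fitted, with 2221 in the Fl2d, 1646 in the CG6422 and 1616 in the double depletion. Fl2d replicate 1 standing apart as the whole cause is argued against by 2789 calls without it. The share of mt:lrRNA is argued against by 3258 calls with it as a covariate (2090 in the CG6422 depletion), and the trend with exon length by 3491 calls with the correction (1178). A wider role of Fl2d than that of the other depleted proteins may account for the count, but a general difference in the state of these cultures was not tested and stays open.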

How the results depend on the processing

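The mt:lrRNA covariate, both libraries with a low mt:lrRNA share left out and the gene length correction were chosen after the data were seen, alone and together with the block. The 7 drops of the targeted transcripts kept direction and call in every alternative. Reversed was 1 value, the cytosolic ribosomal protein list in the YT521 depletion, at adjusted p = 0.876 with the gene length correction (within 2.43e-04 to 0.876 over its alternatives). Counts of genes beyond 1.5 times the main count were as follows, in the order of the text; the cause was not tested unless the alternative itself gives it. With DESeq2's Wald test CG7818 against Ime4 gave 115 (main 42), the double against Ime4 45 (main 13) and the double against CG7818 299 (main 181), and without a filter they gave 176, 76 and 320. With only the 2 compared groups fitted, which leaves fewer libraries to estimate the spread, Ime4 gave 611 (main 311), the double 1616 (955) and Fl2d 2221 (3451), the comparisons within the writer core 226, 174 and 613, and YT521 against CG6422 689 (1077). At an absolute log2 fold change of at least 1, a stricter rule by construction, the 10 counts were 13, 17, 69, 314, 35, 57, 4, 1, 4 and 104. With the mt:lrRNA covariate Ime4 gave 594, CG7818 323 and the comparisons within the writer core 178, 37 and 354, and with both low libraries left out 618, 347, 223, 33 and 391. The higher share of CG7818 against Ime4 was 67.4% and 66.4% in these. The length correction gave 67 for CG7818 against Ime4. With 1 library left out, which also removes information, the counts ranged from 142 to 197 (Ime4), 95 to 122 (CG7818), 461 to 752 (double), 2789 to 3450 (Fl2d), 248 to 495 (YT521), 864 to 1429 (CG6422), 16 to 32 (CG7818 against Ime4), 6 to 10 (double against Ime4), 26 to 61 (double against CG7818) and 679 to 1017 (YT521 against CG6422). Of the 311 genes called for Ime4 311 were also called with the covariate, 295 with the length correction and 299 with DESeq2's Wald test, and of the 545 for YT521 510, 414 and 510.

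The replicate number is shared by the labels of all groups, but it was taken to pair the samples only for the CG7818 and double depletions. This rests on a cut at 0.1 made on the data, which the labels do not give. CG7818 with YT521, at 0.082, 0.158 and 0.278, was left out by this cut. Of 63 correlations between same-numbered libraries' deviations 21 were above 0.1 (range −0.235 to 0.278, median 0.068), although 17 of the 21 libraries correlated best, on average, with their own number, a hint from the data and not the design. With the replicate number as a block CG7818 against Ime4 gave 64 and the double against Ime4 22 genes. The other counts stayed within 1.5 times, at 414, 233, 1096, 3581, 738 and 1791 against the control, 258 for the paired comparison of the double with CG7818 and 1203 between the readers. Of the 181 genes of the paired comparison 181 were also called with the block. The block together with the covariate gave 547 genes there, with both low libraries left out 791 and with the length correction 178. Among the list tests the block ended the call of the writer and reader list in the YT521 depletion (0.0594, within 0.00101 to 0.319 over its alternatives). It gave a call to the muscle markers in the CG6422 depletion (0.0452, within 0.0420 to 0.642). Of 572 named gene values it weakened 2 and strengthened 11.

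Of 150 list tests 29 were called, 5 with an estimated correlation, 42 with fry, 28 with size factors, 29 with the block, 27 with the covariate, 26 with both low libraries out, 21 with the length correction and 26 to 32 with 1 library left out. At an adjusted p under 0.01 all 15 counts of shared genes moved beyond 1.5 times, and 1 of 15 did so with the block. Of 572 named gene values the length correction weakened 40 and strengthened 13, no filter 24 and 16, the fit of 2 groups 15 and 18, both libraries out 11 and 20, and the covariate 1 and 19. DESeq2's Wald test gave a value for 569 of them, with 2 weakened and 10 strengthened, and the stricter filter for 477, with 3 and 5. Over 3432 values with 1 library left out 512 were weakened and 8 strengthened. A depth of 20214568 to 28296393 counts limits genes near 1 CPM, such as SkpB and CG14694, whose calls rest on few counts.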

Other observations

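The test of genes tied to one single depletion and the gene length correction were chosen only after the results were seen, and the tests of long introns, X-linked genes and the double depletion were set beforehand. Besides the genes described so far, single genes of lists that were not called fell in the Fl2d depletion. Of the 22 innate immune genes 1 rose and 10 fell in either adjustment (camera adjusted p = 0.1145). The Hsp70 co-chaperone gene stv fell by 1.03, the heat shock factor gene Hsf by 0.37 and Hsp70Bbb by 1.57, mam, a co-activator of Notch, by 0.64 and N by 0.23, and the NF-kappa-B genes dl and Rel by 0.46 and 0.30. The fructose-bisphosphatase gene fbp fell by 0.84. The reads of mam and Rel overlap other genes, and Hsp70Bbb has near-identical copies.

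Genes that followed one single depletion and the double, but not the other single depletion, and that differed between the single depletions, numbered 18, of which 9 followed CG7818 and 9 followed Ime4. Following CG7818, with values for the CG7818, Ime4 and double depletions, were Nt5b (−0.95, −0.06 and −0.75), RpL7A (−0.65, −0.03 and −0.46) and CG14694 (−2.02, −0.10 and −1.18). Following Ime4, with values for the Ime4, CG7818 and double depletions, were LanB1 (−0.54, 0.03 and −0.59), LanB2 (−0.27, 0.04 and −0.31), Sap-r (−0.39, 0.05 and −0.33) and, as the 1 gene that rose, aos (0.35, −0.10 and 0.31). Of the 18 genes 17 were lower (exact two-sided binomial p = 1.45e-04, with genes treated as independent, which they are not). Fewer genes met these conditions without single libraries, 10 without Ime4 replicate 1, 10 without Ime4 replicate 2, 11 without CG7818 replicate 2 and 8 without CG7818 replicate 3, and each of them was lower. Without each other library 13 to 18 were lower, with at most 1 higher. With the gene length correction 11 followed CG7818 and 16 followed Ime4, of which 25 were lower. Of the 18 genes 9 were also called in the same direction in at least 1 of the Fl2d, YT521 and CG6422 depletions, 3 of those that followed CG7818 and 6 of those that followed Ime4. LanB2 was at −0.17, −0.40 and −0.22 in the Fl2d, YT521 and CG6422 depletions and Sap-r at −0.44, −0.31 and −0.48. LanB1 fell by 0.28 in the YT521 and by 0.21 in the CG6422 depletion and Nt5b by 0.23 in the CG6422 depletion, where aos rose by 0.55. Called in the opposite direction in at least 1 of these 3 depletions were 5 of the 18, 2 that followed CG7818 and 3 that followed Ime4. RpL7A was among them and rose in the Fl2d depletion, by 0.26. The 9 genes not called in the same direction elsewhere were all lower in the depletion they followed, though some of them rose in the Fl2d depletion. Whether a depletion lowered transcripts other than its target or each protein has a separate function stays open, since the direction does not tell these apart and sequences of the depletion reagents were not analysed here.

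Genes with more than 20 kb outside exons (471 against 7712 others) shifted by a difference of medians over 0.05 in 3 of the 6 depletions, which were the double (−0.088), the Fl2d (−0.114) and the CG6422 (−0.137) depletions. Within deciles of exon length, over 428 genes in 3 deciles, the difference was −0.065 in the double, −0.073 in the Fl2d and −0.009 in the CG6422 depletion, and −0.094 in the CG7818 depletion. With the gene length correction, over all 471 genes, it was −0.034 in the double, −0.021 in the Fl2d, 0 in the CG6422 and −0.062 in the CG7818 depletion, and 0.038 in the YT521 depletion against −0.033 before. The deciles and the correction thus differ for the double and Fl2d depletions, so whether a shift remains beyond the trend with exon length stays open there. With 1 library left out the difference ranged from −0.111 to −0.063 in the double and from −0.168 to −0.079 in the CG6422 depletion, nearest to 0 without CG6422 replicate 2. In the Fl2d depletion it was −0.037 without Fl2d replicate 1, one of the libraries low in mt:lrRNA, and −0.15 to −0.093 without each other library. It passed 0.05 in the CG7818 depletion without CG7818 replicate 3 (−0.093) or Control replicate 3 (−0.054), against −0.007 without CG7818 replicate 2. In the YT521 depletion it did so without YT521 replicate 3 (−0.071), against 0.001 without YT521 replicate 2, which is low in mt:lrRNA.

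A shift of X-linked genes (1446 against 6718) by over 0.05 was found in 0 of the 6 depletions, with the difference of medians farthest from 0 being 0.043 in the CG6422 depletion. Whether the double depletion moves the genes of the single depletions farther stays open. Of 193 genes called in the CG7818 depletion 46.6% had a larger change in the double depletion, but these genes were chosen for their size in the single depletion, which inflates it there and lowers that share. Their median absolute log2 fold change was 0.43 in the double and 0.39 in the CG7818 depletion. For Ime4 it was 57.1% of 310 genes, with 0.34 and 0.32.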
